A study of Oryctolagus cuniculus with 12 samples.

How the data were processed

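The series holds 12 RNA sequencing libraries of rabbit cornea, 3 each labelled control, blue_light, GL and RL. Per the labels the rabbits were 6 months old and on a normal diet, RNA was extracted with an RNeasy kit and libraries were made with a SMARTer mRNA-seq kit. The same treatment text, light exposure for 6 weeks, stands on all 12 libraries, controls included. Wavelength and intensity are not given in the sources used here, and the labels do not spell out GL and RL. The submitters' processing notes name GRCm38/mm10, a mouse build, whereas the deposited table places genes on rabbit RefSeq chromosome sequences with OryCun2.0 numbering. The numbers were therefore taken as rabbit genes, and the build stays unnamed in the sources used here.

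The authors deposited an estimated count and an FPKM value per gene and library, per the file headers. Of 29076 genes listed, 7628 had a count of 0 in every library. Gene names were compared with a RefSeq gene table, used for names only: 20171 of 23890 numeric gene identifiers were in it and 18461 carried the same symbol. Another 450 entries repeated a gene name and were kept apart by identifier. Genes lay on 1437 sequences, 22 of them chromosomes.

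Counts were whole numbers, so rounding moved nothing. For each gene the ratio of count to FPKM was the same in every library, up to a factor per library (SD 0.000659 log2 over 10345 genes). Low counts piled up at regular steps, with 2679 values of 4 against 851 of 3 and 626 of 5, and 2254 of 8 against 897 of 7 and 638 of 9. The best-matching step was 3.73, so 1 fragment was taken to stand for about 3.73 counts. The pile at 8 lies higher than that step would put it, so the step, and the fragments and floors resting on it, are approximate. Dividing by that step left an estimated 11.0 to 17.4 M (mega) fragments per library. A detection floor of 3 fragments corresponded to 0.173 to 0.273 CPM. All 140000 zero counts had an FPKM of 0.0001. The libraries carry no molecular identifiers, so standard errors and floors cover counting error and the spread between samples but not losses before sequencing.

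Before the data were examined, the plan named limma on log2(FPKM + 1), and edgeR if the table held raw counts. The table held estimated counts beside FPKM. On these counts edgeR quasi-likelihood fits (glmQLFit, glmQLFTest) with TMM scaling and filterByExpr were used. Limma became an alternative. This departs from the plan, since estimated counts that step by about 3.73 per fragment are not raw counts. The version divided by the step was run as well, and the counts of the planned limma test are given with the alternatives. All 12 libraries shared one fit with 4 group means, and 18171 genes were tested, 5167 of them without a gene symbol. TMM factors ran from 0.944 to 1.06 and the biological coefficient of variation was 0.578. CPM values are counts scaled by TMM-adjusted library size. Tests covered each light group minus control, the 3 differences between light groups, the mean of the light groups minus control, and any difference among the 4 groups. A gene counted as changed at a Benjamini-Hochberg (BH) adjusted p below 0.05 within its comparison.

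A set of 46 gene lists was fixed for cell types, light response, stress, matrix and metabolism; 45 were tested, since the mitochondrially encoded list matched no gene. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it, and members were also adjusted over the list alone.

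Genes were named by rule. For each light group against control these were the 8 higher and 8 lower genes with a symbol, past the threshold, with non-overlapping groups and the largest fold. Empty places were filled by the smallest unadjusted p, as values without a claim of change. Comparisons between light groups and the mean took 3 and 3, and each list up to 4 members with the smallest p. A fixed set of 15 corneal, clock and opsin genes was always looked up, of which ALDH3A1 and DBP had no entry by that name and were not analysed here. Genes without a symbol, and DIP2C in GL against RL, are named outside the rule, chosen after their values were seen.

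Alternatives fixed with the plan covered scaling, filtering, DESeq2, array weights, blocking by replicate number, fits of only the groups compared and omission of each library. Alternatives chosen after the data were seen were log2 library size as a covariate, a covariate for 2 sets of libraries, a fit of 7 libraries alone, omission of 3 libraries with retinal transcripts, and the step-divided counts. Labels were also exchanged among libraries, with all 10 splits of a 3-against-3 comparison and 100 drawn splits for the tests over more groups. Shared controls were simulated 20 times.

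The procedure was tried on data with known changes placed in 200 of 18171 genes at 2-, 4- and 8-fold. In GL against control, 16.4%, 56.7% and 72.7% of these were called with 6 false calls. In blue_light against control the shares were 13.4%, 55.2% and 63.6% with 7 false calls, and in RL against control 13.4%, 64.2% and 69.7% with 3. A 2-fold change is therefore mostly missed by these tests. GC content was not analysed here, as no genome sequence was used. Fits used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0; summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.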

Results

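RNA from rabbit cornea was counted in 12 libraries, 3 each from controls and from groups labelled blue_light, GL and RL. Per the labels, light exposure lasted 6 weeks. Total counts per library, in M (mega), were 49.4 ± 6.61 in control, 48.5 ± 9.23 in blue_light, 63.6 ± 1.73 in GL and 56.8 ± 9.501 in RL (mean ± SD, n = 3 each; exact permutation p = 0.142 over 15400 partitions of the libraries). The labels do not say whether libraries came from separate animals, so p-values here measure the spread between these samples, which may be technical. Correlation between libraries had a median of 0.907 within groups and 0.895 between groups.

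Corneal transcripts were abundant in every group. KRT12, a keratin of the corneal epithelium, stood at 18035 ± 3751 CPM in control, 18892 ± 2141 in blue_light, 23861 ± 357 in GL and 24843 ± 4107 in RL. Its partner KRT3 stood at 5344 ± 436, 5010 ± 1120, 7001 ± 177 and 6761 ± 2238 CPM in the same order. KRT5 of basal cells stood at 1403 ± 94.0, 1122 ± 457, 1902 ± 53.4 and 2490 ± 949. Among stromal genes, KERA stood at 4770 ± 1534, 5831 ± 798, 4477 ± 350 and 4637 ± 1013 CPM. LUM stood at 3957 ± 749, 5144 ± 539, 4166 ± 386 and 4795 ± 674, and the collagen gene COL1A1 at 7681 ± 2773, 6311 ± 5277, 15323 ± 1633 and 10608 ± 7037. PAX6, a transcription factor of eye development, stood at 440 ± 25.6, 425 ± 106, 359 ± 40.6 and 406 ± 140 CPM. None of these passed the edgeR threshold in any comparison.

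Other eye tissue was uneven over single libraries. The mean log2 CPM of the retina list was 1.35 in blue_light replicate 1, 1.28 in control 2 and 3.79 in GL 3. These are the 3 libraries with retinal transcripts named below, though others held some. The list stood at 0.19 in RL 2, −0.142 in blue_light 2 and −0.258 in blue_light 3, and at −2.71 to −1.77 in the rest. CRYAA, a lens crystallin, ranged from 205 to 5202 CPM. A further difference concerned rare transcripts: 5 libraries (all blue_light, control 1, RL 1) had 2389 to 2563 genes at counts of 1 to 20, the 7 others 767 to 1461. With groups in the fit, 1 gene differed between these sets by edgeR, NFAT5 (log2 2.75, adjusted p = 0.0201, higher in the 5), and 3462 of 18171 genes had an unadjusted p below 0.05.

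**Figure D1:**
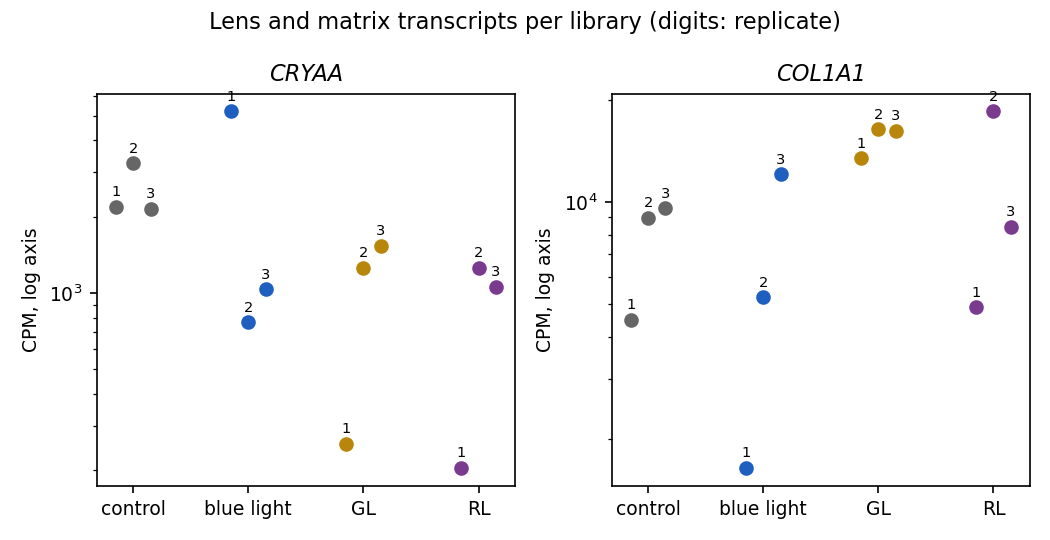
CRYAA and COL1A1 in each of the 12 libraries, in CPM on a log axis. CRYAA ranges from 205 to 5202 CPM.

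Blue light was set against control to ask which transcripts differ after that illumination, and 3 of 18171 genes changed by edgeR, 2 up and 1 down. LOC100344965, annotated as coupling factor 6 of the mitochondrial ATP synthase, rose from 5.08 ± 0.726 to 26.6 ± 4.03 CPM (n = 3 each, log2 2.39 ± 0.23 SE, adjusted p = 0.00163), while the main gene ATP5J stood at 90.9 ± 13.6 in control and 62.0 ± 5.89 in blue_light. LOC100344261, annotated as similar to adenosylhomocysteinase, an enzyme of the methylation cycle, fell from 31.3 ± 10.5 to 5.53 ± 0.764 CPM (log2 −2.50 ± 0.33, adjusted p = 0.0275), with AHCY itself at 505 ± 28.2 and 502 ± 62.9. LOC100339782, a partial copy of a histone-lysine methyltransferase gene, was 0 in every control and 9.44 ± 1.76 CPM in blue_light, at least 38.8-fold above a floor of 0.244 CPM (adjusted p = 0.000160), and its call ended in 1 of 22 alternatives, a limma fit with a block for replicate number (0.0541). Its namesake KMT2A stood at 167 ± 18.1 and 172 ± 12.4. Each of the 3 genes separated all blue_light libraries from all controls, a separation that chance gives for 10% of genes. They lack a symbol and were chosen after their values were seen, and their values are uncertain, as reads may be shared with the main genes. The sum of 7 coupling factor 6 copies was 113 ± 16.3 CPM in control and 104 ± 10.9 in blue_light. The call of LOC100344261 ended in 9 of 23 alternatives (adjusted p 0.0541 to 1), among them omission of blue_light 1 (0.218), 2 (0.142) or 3 (0.335) or control 2 (0.166) or 3 (0.0697) and a covariate for library set (log2 −2.07 ± 0.32, 0.148). Without the 3 libraries with retinal transcripts LOC100344965 had an adjusted p of 0.297. The count became 10 without control 1, 8 by limma with array weights and 29 with DESeq2, and 592 genes had an unadjusted p below 0.05.

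Cell cycle genes stood higher in blue_light as a group (24 of 31, median log2 0.62; camera adjusted p = 3.85e-06), but adjusted p = 0.927 with an estimated correlation. CDK1, which drives entry into mitosis, stood at 11.6 ± 3.93 CPM in control and 22.9 ± 3.28 in blue_light, HMMR at 2.83 ± 1.34 and 9.44 ± 2.61, and the spindle factor TPX2 at 15.04 ± 8.84 and 30.8 ± 5.27. Control 1, in the set of 5 with all blue_light libraries, had a mean log2 CPM of 3.78 for this list, inside the blue_light range of 3.61 to 4.04, against 2.65 and 3.07 in control 2 and 3, and with the set covariate the adjusted p was 0.0393. Retinal genes stood higher (16 of 19, adjusted p = 0.0299), with adjusted p = 0.948 with an estimated correlation. The call ended in 10 of 21 settings: without blue_light 1 (0.199), control 1 (0.382) or control 3 (0.261), among genes of mean FPKM 5 or more (0.461) and in all 6 limma settings (0.0783 to 0.502). Without the 3 retinal libraries, among them blue_light 1 and control 2, it had 2.29e-11. In the clock list, adjusted over the list alone, ARNTL was higher (28.5 ± 7.04 and 48.0 ± 3.56 CPM; log2 0.75 ± 0.19, edgeR adjusted p = 0.0376) and its repressor NR1D1 lower (106 ± 25.2 and 46.5 ± 2.82; log2 −1.19 ± 0.35, 0.0468). In the adipocyte list, adjusted over the list alone, the lipase LPL was lower (42.7 ± 37.7 and 2.39 ± 1.58 CPM; adjusted p = 0.00177). No list member passed edgeR over all genes in any comparison.

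Values without a claim of change follow for genes with symbols that separated blue_light from control. Higher in blue_light than in control were TTC9 (69.3 ± 9.36 against 13.8 ± 5.25 CPM), MPP7 (73.4 ± 8.18 against 39.5 ± 6.45), the ubiquitin ligase TRIM25 (35.8 ± 2.19 against 15.6 ± 5.37). So were TSTD2 (55.6 ± 13.4 against 27.7 ± 7.86), the mitochondrial carrier SLC25A24 (67.7 ± 3.77 against 45.8 ± 4.44), CMC2 (17.1 ± 2.10 against 7.98 ± 1.60) and the mitotic kinesin KIF14 (17.96 ± 3.53 against 6.77 ± 3.71). Lower were PADI3 (19.1 ± 23.9 against 132 ± 33.2), KCNAB1 (21.0 ± 6.38 against 54.4 ± 3.72), SELENBP1 (97.2 ± 25.3 against 235 ± 42.0). Also lower were CLIC5 (1.43 ± 0.186 against 7.99 ± 4.04), the adhesion molecule VCAM1 (0.520 ± 0.150 against 4.05 ± 0.592), CCDC69 (24.3 ± 1.83 against 39.1 ± 5.30) and the matrix proteoglycan SPOCK2 (19.6 ± 0.785 against 31.7 ± 4.12).

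GL against control gave 10 changed genes of 18171 by edgeR, 1 up and 9 down. HSPA13, a member of the HSP70 chaperone family, fell from 49.8 ± 1.63 to 14.1 ± 4.09 CPM (n = 3 each, log2 −1.82 ± 0.24, adjusted p = 0.0142), with every GL library below every control. RPL39, which encodes a protein of the large ribosomal subunit, fell from 254 ± 73.7 to 56.1 ± 7.14 CPM (log2 −2.18 ± 0.33, adjusted p = 0.0404), likewise in 3 of 3 libraries. RL libraries also lay below every control for RPL39, at 64.1 to 141 CPM against 169 to 297, without a call in RL minus control. LOC100339782 was 0 in every control and 7.69 ± 1.98 CPM in GL, at least 31.6-fold above the floor (adjusted p = 0.000205). LOC100344261 fell from 31.3 ± 10.5 to 6.21 ± 1.41 (log2 −2.34 ± 0.33, adjusted p = 0.0209), with AHCY itself at 505 ± 28.2 and 765 ± 23.9. HSPA13 lost its call in 6 of 24 alternatives (0.0602 to 0.223), among them omission of control 2 (0.0602) or 3 (0.0684) or GL 1 (0.0753) and depth as a covariate (log2 −1.58, 0.168). RPL39 lost its call in 9 of 24 (0.0537 to 0.772), among them omission of control 2 (0.146) or 3 (0.199) or GL 1 (0.184), 2 (0.0919) or 3 (0.281) and the set covariate (log2 −2.15 ± 0.35, 0.0609). LOC100344261 lost it in 8 of 24 (0.0543 to 0.691), among them control 2 (0.112) or 3 (0.0684) or GL 1 (0.107), 2 (0.0589) or 3 (0.108).

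The 6 other genes lower in GL were all annotated as copies of ribosomal protein L17, and near-identical copies share reads, so their values are uncertain. LOC100339314 went from 382 ± 205 to 20.1 ± 7.16 CPM (log2 −4.25 ± 0.48, edgeR adjusted p = 0.00511), LOC100355297 from 89.7 ± 15.2 to 6.59 ± 2.73 (−3.77 ± 0.35, 0.00105). LOC100339582 went from 128 ± 27.5 to 23.6 ± 3.44 (−2.43 ± 0.32, 0.0142). LOC100350920 (log2 −3.54, adjusted p = 0.0209), LOC100354651 (0.0142) and LOC100355319 (0.0404; 0.0577 with the set covariate) were rarer. In GL, LOC100354651 stood at 0.0265 and LOC100355319 at 0.0689 CPM, below a floor of 0.173 CPM, so their fitted folds depend on the prior count. Over the alternatives these log2 folds ranged from −9.04 to −2.82 and from −5.93 to −1.97. In all 6, each GL library lay below each control. LOC100355319 lost its call in 11 of 23 alternatives (0.0576 to 0.425), among them control 2 (0.141) or 3 (0.140) or GL 1 (0.273), 2 (0.0598) or 3 (0.0576). LOC100350920 lost it in 8 of 24 (0.0617 to 0.664), among them control 2 (0.0745) or 3 (0.0748) or GL 1 (0.107), 2 (0.0642) or 3 (0.143). LOC100339582 lost it in 6 of 24 (0.0617 to 0.271), among them control 3 (0.0684) or GL 1 (0.107) or 3 (0.0617), and LOC100354651 in 3 of 24 (0.107 to 0.135), among them GL 1 (0.107). LOC100339314 lost it in 2 of 24 (0.0611 and 0.223) and LOC100355297 in 1 (0.104). These copies summed to 614 ± 192 CPM in control and 51.0 ± 3.28 in GL, while the family of 29 copies summed to 1260 ± 193 and 1108 ± 52.5. One copy, LOC108175352, held 92.3% to 93.2% of the family in GL and at most 55.8% elsewhere. The count of 10 became 21 without GL 2 or without control 1, 3 without GL 1, 6 without GL 3, 5 without control 2, 4 without control 3, 131 by limma with array weights and 147 with DESeq2 (55 up, 92 down). By edgeR 1472 genes had an unadjusted p below 0.05.

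**Figure D2:**
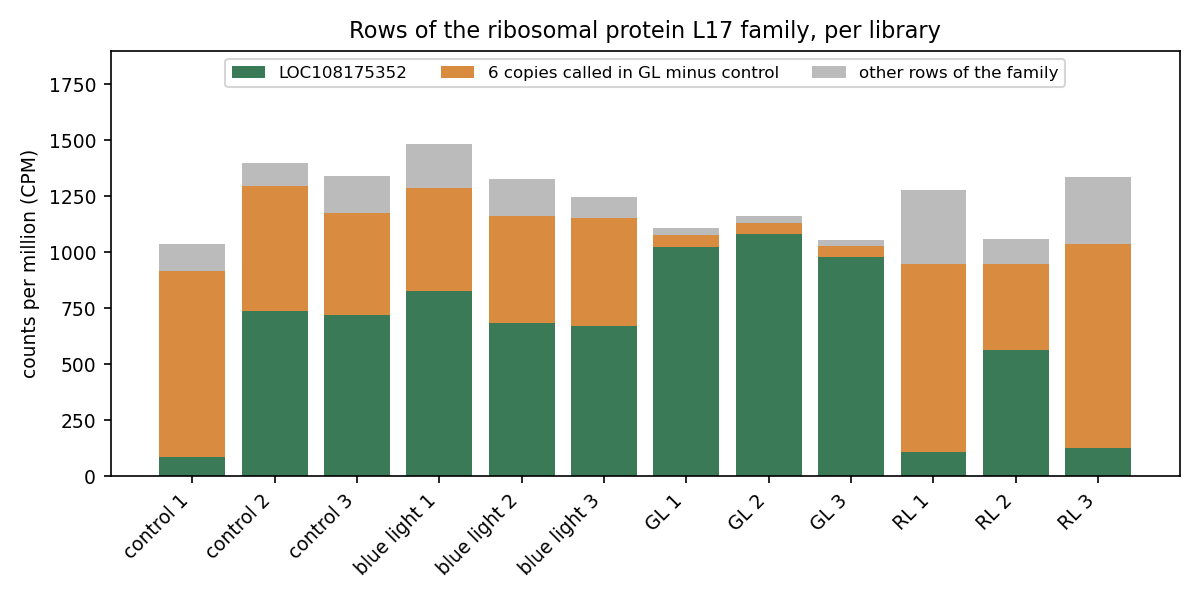
Stacked CPM of the RPL17 copies in each library: LOC108175352, the 6 called copies, and the other copies. The family sum is 1260 ± 193 in control and 1108 ± 52.5 in GL, while LOC108175352 holds 92.3% or more of it only in GL.

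Lens genes stood lower in GL in all 16 of 16 (median log2 −1.63; camera adjusted p = 8.17e-09; LENEP lower when adjusted over the list alone, 0.0174), but adjusted p = 0.891 with an estimated correlation. Immediate early genes, transcribed within minutes of a stimulus, stood lower (14 of 21, adjusted p = 0.00437; adjusted p = 0.891 with an estimated correlation). FOS stood at 477 ± 274 CPM in control and 93.8 ± 23.7 in GL (log2 −2.35 ± 0.55) and DUSP1 at 243 ± 132 and 70.1 ± 26.5, both lower when adjusted over the list alone. The list call ended without control 2 (0.0906), without GL 3 (0.0970), without the 3 retinal libraries (0.343) and in 4 limma settings (0.0503 to 0.0904). Cell cycle genes stood higher (25 of 31, adjusted p = 0.00306; adjusted p = 0.891 with an estimated correlation), though not without control 2 (0.118) or GL 1 (0.0824) or among genes of mean FPKM 5 or more (0.0977). Control 1 (mean log2 CPM 3.78) lay inside the GL range of 3.32 to 3.85, and control 2 and 3 (2.65 and 3.07) below it. Keratocyte genes stood higher (16 of 21, 0.0124; adjusted p = 0.891 with an estimated correlation), with the matrix protein PRELP at 192 ± 77.5 and 390 ± 83.8, though not without control 1 (0.128) or with the set covariate (0.0653), and with the sign turned with library size as a covariate (0.832). Epithelial genes stood higher (16 of 21, 0.0190; adjusted p = 0.891 with an estimated correlation), with the water channel AQP5 at 2857 ± 79.9 and 4573 ± 339, though not without control 1 (0.0572), control 2 (0.0723) or GL 2 (0.0944). This list also lost its call with library size (0.527) or library set (0.167) as a covariate. Among genes of mean FPKM 5 or more keratocytes had 0.0737 and epithelium 0.0977, and both calls ended in limma settings (0.0503 to 0.150), 4 for keratocytes and 5 for epithelium.

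Retinal genes (18 of 19) and cholesterol synthesis genes (14 of 19) stood higher in GL, both with camera adjusted p = 0.0386 and adjusted p = 0.891 with an estimated correlation. The retinal call ended without control 1 (0.419), control 3 (0.223) or GL 3 (0.356, where the sign turned), with library size (0.732) or set (0.375) as a covariate, within the 7 libraries (0.563) and without the 3 retinal libraries (0.343). The cholesterol call ended without control 1 (0.430), control 2 (0.0723), GL 1 (0.438) or GL 3 (0.0970), with library size (0.822, the sign turned) or set (0.623) as a covariate, within the 7 libraries (0.348) and without the retinal libraries (0.159). Among genes of mean FPKM 5 or more retina had 0.390 and cholesterol 0.123, and step-divided counts gave 0.0590 for both. In limma settings 5 ended the retinal call (0.137 to 0.289) and all 6 the cholesterol call (0.112 to 0.289), and an edgeR block for replicate number gave 0.0965 for retina. Adjusted over the list alone, the sodium channel SCN7A (8.38 ± 2.06 in control, 3.17 ± 0.521 in GL; edgeR adjusted p = 0.0365) was lower. Values without a claim of change were, higher in GL than in control, LPAR3 (74.5 ± 12.3 against 27.1 ± 9.76 CPM), the hyaluronan-degrading CEMIP (1135 ± 146 against 559 ± 92.6), PNPLA6 (71.7 ± 9.78 against 38.1 ± 6.90), the homeobox gene DLX3 (28.9 ± 4.0003 against 11.8 ± 0.981). So were TRIM25 (33.7 ± 1.37 against 15.6 ± 5.37), the adhesion molecule SDK1 (22.4 ± 4.86 against 7.25 ± 2.11), the membrane protease HPN (46.3 ± 11.4 against 22.3 ± 2.88) and TMEM30B (28.0 ± 4.20 against 14.4 ± 0.696). Lower were PLSCR4 (19.6 ± 0.370 against 62.2 ± 13.3), ZNF248 (4.25 ± 2.63 against 18.6 ± 2.51), PHACTR2 (85.05 ± 23.3 against 182 ± 35.3). Also lower were CHAT, which makes acetylcholine (10.3 ± 2.52 against 65.8 ± 36.9), ATP6AP1L (3.57 ± 1.31 against 10.7 ± 2.24) and GAS2L2 (0 against 1.10 ± 0.601).

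RL against control gave 2 changed genes of 18171 by edgeR, 1 up and 1 down. TEAD1, a transcription factor that binds DNA for the Hippo pathway, fell from 213 ± 17.97 to 27.9 ± 11.6 CPM (n = 3 each, log2 −2.93 ± 0.26, adjusted p = 0.000580), with 3 of 3 RL libraries below every control, and stood at 222 ± 32.4 in blue_light and 225 ± 23.8 in GL. No alternative of 24 ended this call. LOC100339782 was 0 in every control and 7.496 ± 2.82 CPM in RL, at least 30.8-fold above the floor (adjusted p = 0.000212). Its call ended in 3 of 23 alternatives (0.0978 to 0.137). The count of 2 became 9 without control 1, 4 without RL 2, 39 by limma with array weights and 87 with DESeq2 (31 up, 56 down), and 861 genes had an unadjusted p below 0.05.

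**Figure D3:**
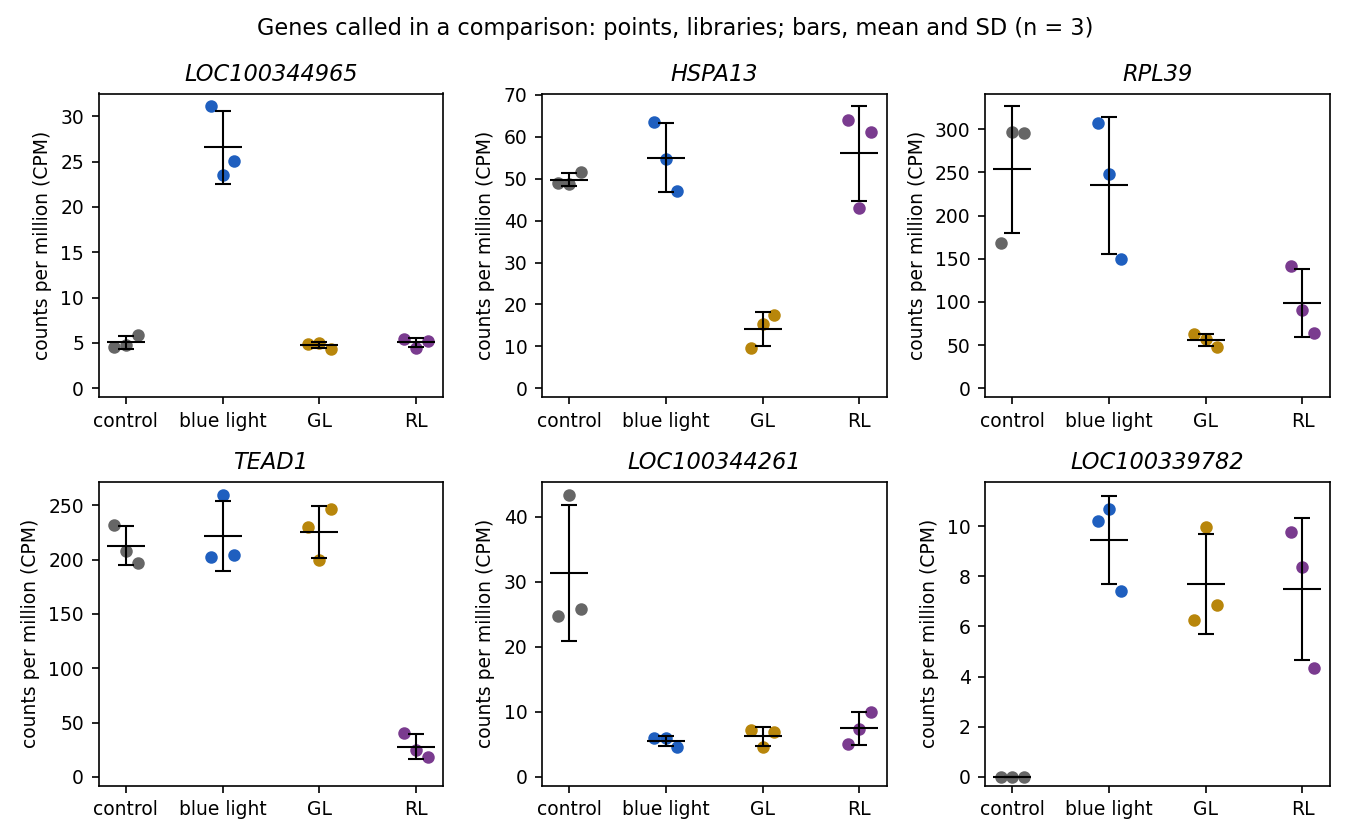
CPM of LOC100344965, HSPA13, RPL39, TEAD1, LOC100344261 and LOC100339782 in each library, with group mean and SD. TEAD1 falls to 27.9 ± 11.6 CPM in RL only, and HSPA13 to 14.1 ± 4.09 in GL only.

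Cholesterol and fatty acid synthesis genes stood higher in RL in 18 of 19 (median log2 0.46; camera adjusted p = 1.71e-11), but adjusted p = 0.377 with an estimated correlation. HMGCS1, an early synthase of the pathway, stood at 110 ± 30.1 CPM in control and 252 ± 51.9 in RL (log2 1.20 ± 0.30, edgeR adjusted p = 0.0319 when adjusted over the list alone). SQLE stood at 76.2 ± 15.04 and 112 ± 17.8, ACSS2 at 26.1 ± 2.49 and 47.4 ± 11.5, and STARD4 at 20.6 ± 1.66 and 38.5 ± 13.4. Lens genes stood lower in 16 of 16 (median log2 −1.51; 2.84e-12; adjusted p = 0.377 with an estimated correlation). Cell cycle genes stood higher in 23 of 31 (1.84e-05; adjusted p = 0.377 with an estimated correlation), with CCNB1 (6.90 ± 1.94 in control, 17.2 ± 3.63 in RL) and UBE2C (6.10 ± 1.67 and 15.6 ± 5.90) higher when adjusted over the list alone (both 0.0229). Here too control 1 (mean log2 CPM 3.78) lay inside the RL range of 3.52 to 3.85, with control 2 and 3 (2.65 and 3.07) below it. Epithelial genes stood higher in 19 of 21 (0.000393), interferon response genes in 20 of 23 (0.000530; 0.412 among genes of mean FPKM 5 or more), both with adjusted p = 0.377 with an estimated correlation. Barrier and cornification genes stood higher in 19 of 26 (0.000530; 0.0618 without control 1; adjusted p = 0.377 with an estimated correlation), among them IVL of the cornified envelope (3.04 ± 1.99 and 23.0 ± 20.1). Adipocyte genes stood lower in 5 of 6 (0.00382; 0.0733 without RL 1; adjusted p = 0.377 with an estimated correlation), with LPL (42.7 ± 37.7 and 2.13 ± 1.08) and CIDEA lower when adjusted over the list alone (0.00136 and 0.0458). Heat shock genes stood higher in 16 of 18 (0.0114; 0.0739 without control 1, 0.1004 without RL 3, 0.186 by limma after quantile scaling; adjusted p = 0.377 with an estimated correlation), with HSPB8 at 36.2 ± 21.0 and 102 ± 49.9.

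**Figure D4:**
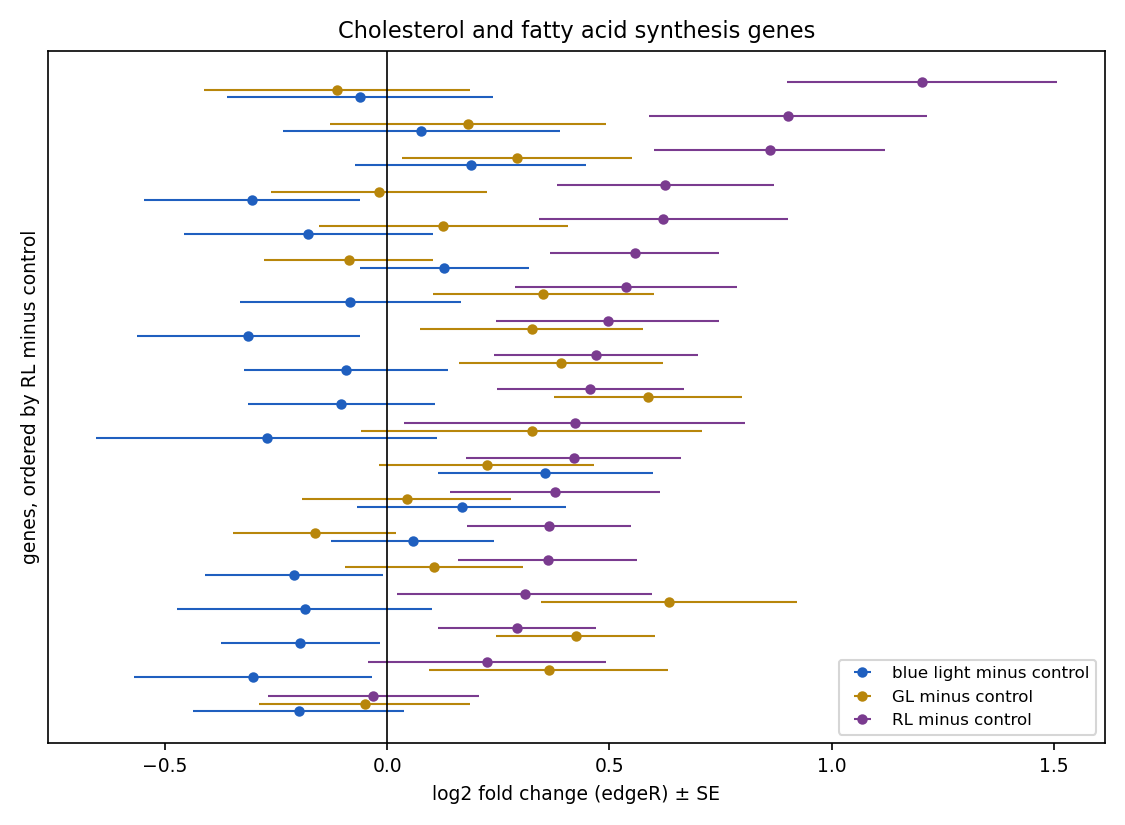
Log2 fold change ± SE of 19 cholesterol and fatty acid synthesis genes, ordered by RL, in each light group against control. In RL 18 of 19 lie above 0, in GL 14.

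Angiogenesis factors stood higher in RL in 16 of 20 (camera adjusted p = 0.0154; adjusted p = 0.497 with an estimated correlation), though not without control 1 (0.122), control 3 (0.109), RL 2 (0.148) or RL 3 (0.0517) or with library size as a covariate (0.280). Immediate early genes stood higher in 18 of 21 (0.0268; adjusted p = 0.784 with an estimated correlation), though not without control 1 (0.195), control 3 (0.238) or RL 3 (0.582, where the sign turned) or with library size as a covariate (0.892), among genes of mean FPKM 5 or more (0.115) or by limma after quantile scaling (0.0799). Oxidative stress genes stood higher in 19 of 28 (0.0409; adjusted p = 0.633 with an estimated correlation), though not without control 1 (0.284), control 3 (0.0651), RL 2 (0.216) or RL 3 (0.582) or with library size as a covariate (0.656). This call ended in 12 of 21 settings, the others being all 6 limma settings (0.0987 to 0.364) and step-divided counts (0.0507). RARRES1, a retinoid-responsive gene, was higher when adjusted over the list alone (251.5 ± 22.6 CPM in control, 442 ± 30.2 in RL; edgeR adjusted p = 0.00484). Values without a claim of change were, higher in RL than in control, PNPLA6 (65.1 ± 2.93 against 38.1 ± 6.90), KRT20 (43.7 ± 17.5 against 5.21 ± 4.41). So were the sterol enzyme MSMO1 (188 ± 36.1 against 101 ± 14.96), the matrix protein DPT (140 ± 19.1 against 61.2 ± 2.25) and SVBP (72.9 ± 11.7 against 38.6 ± 5.40). Lower were DIP2C (18.7 ± 2.91 against 42.2 ± 5.10), ZBTB10 (15.2 ± 4.94 against 39.6 ± 3.55) and the membrane repair gene DYSF (0.856 ± 0.532 against 5.36 ± 1.62). NYX, RYR1 and EFCAB6 were 0 in RL.

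Blue light against GL gave 9 changed genes of 18171 by edgeR, 7 up and 2 down. HSPA13 stood at 55.0 ± 8.24 CPM in blue_light and 14.1 ± 4.09 in GL (n = 3 each, log2 1.96 ± 0.24, adjusted p = 0.0124). TMEM30B, a subunit of lipid flippases, stood lower in blue_light (10.4 ± 2.05 against 28.0 ± 4.20; log2 −1.43 ± 0.21, adjusted p = 0.0278), as did SPOCK2 (19.6 ± 0.785 against 48.0 ± 5.06; −1.29 ± 0.18, 0.0205). LOC100344965 stood higher (26.6 ± 4.03 against 4.75 ± 0.350; 2.48 ± 0.23, 0.00107). So did the RPL17 copies LOC100339314 (log2 3.66, 0.0145), LOC100355297 (3.77, 0.00107), LOC100350920 (3.54, 0.0205), LOC100354651 (0.0157; fitted log2 2.60 to 8.68 over the alternatives) and LOC100339582 (2.29, 0.0205). In all 9 the groups did not overlap. All blue_light libraries lay in the set of 5 and all GL libraries in the set of 7. With that set as a covariate edgeR left no call (HSPA13 log2 1.83 ± 0.34 with adjusted p 0.253, TMEM30B −1.37 ± 0.29 with 0.343, SPOCK2 −1.03 ± 0.22 with 0.377, LOC100344965 2.51 ± 0.34 with 0.117), with 1264 genes at an unadjusted p below 0.05 and 125 calls by DESeq2. Without the covariate there were 372 calls by DESeq2 and 2702 genes at an unadjusted p below 0.05. The count was 3 without blue_light 1 (HSPA13 0.0538, TMEM30B 0.224, SPOCK2 0.169), 4 without GL 1 and 22 without GL 2. TMEM30B lost its call in 10 of 23 alternatives (0.0514 to 0.986), among them blue_light 2 (0.0514) or 3 (0.127) or GL 1 (0.120) or 3 (0.166). SPOCK2 also lost it in 10 (0.0511 to 0.888), among them blue_light 2 (0.0658) or 3 (0.125) or GL 1 (0.0530), 2 (0.0511) or 3 (0.101). LOC100350920 (0.0621 to 0.737) and LOC100339582 (0.0559 to 0.476) each lost it in 8, with 0.0937 and 0.0814 without blue_light 1, 0.0647 and 0.0658 without blue_light 2, 0.105 and 0.135 without GL 1, 0.0621 and 0.0559 without GL 2, and 0.133 and 0.101 without GL 3. LOC100354651 had 0.0538 without blue_light 1 and 0.105 without GL 1, and LOC100339314 0.101 without GL 3.

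Stromal keratocyte genes stood lower in blue_light than in GL in 15 of 21 (camera adjusted p = 0.00667), Wnt genes in 21 of 31 (0.0109; SFRP1, a Wnt antagonist, 31.4 ± 11.8 against 69.2 ± 13.2 CPM) and cholesterol genes in 14 of 19 (0.0109), each with adjusted p = 0.837 with an estimated correlation. Glycolysis genes were called lower (21 of 27, 0.0226) with a median log2 of −0.23 but a mean of 0.03, the opposite sign, and adjusted p = 0.837 with an estimated correlation. Lens genes stood higher in 16 of 16 (0.0109; adjusted p = 0.914 with an estimated correlation). With the set covariate the values were 0.239 for keratocytes, 0.602 for Wnt, and 0.520 for cholesterol and 0.599 for glycolysis with the sign turned, and 5.68e-13 for lens. With library size as a covariate they were 0.654 for keratocytes, 0.454 for Wnt, 0.810 for cholesterol and 0.881 for glycolysis, and without the 3 retinal libraries 0.265 for keratocytes, Wnt and lens, 0.126 for cholesterol and 0.292 for glycolysis. Omission of blue_light 1 gave 0.922 for lens, 0.0890 for keratocytes and 0.0603 for Wnt. Omission of GL 1 gave 0.377 for lens and 0.151 for cholesterol, and glycolysis had 0.0625 without blue_light 3 and 0.171 without GL 3. Genes of mean FPKM 5 or more gave keratocytes 0.101, Wnt 0.276, cholesterol 0.213, glycolysis 0.232 and lens 0.0747. Limma after quantile scaling gave keratocytes 0.0924 and Wnt 0.0541, and all 6 limma settings ended cholesterol (0.0576 to 0.2998) and glycolysis (0.0575 to 0.224), 5 of them lens (0.0541 to 0.144). Adjusted over the list alone, lower in blue_light were KRT8 (29.9 ± 10.2 against 81.1 ± 12.5 CPM; 0.00372), NR1D1 (46.5 ± 2.82 against 118 ± 25.1; 0.0290), the clock output factor TEF (126 ± 25.0 against 230 ± 48.3; 0.0290). So were the opsin OPN3 (36.3 ± 5.32 against 80.8 ± 29.0; 0.0297), TGFBI (log2 −0.72; 0.0365) and NGFR (0.0472). Higher were CRY1 (49.0 ± 3.32 against 34.2 ± 5.27; 0.0408) and ASPN (0.0365). SLC25A24 (67.7 ± 3.77 against 38.5 ± 1.10) and ARHGEF28 (40.55 ± 4.40 against 74.1 ± 1.85) are values without a claim of change.

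Blue light against RL gave 2 changed genes of 18171 by edgeR, both higher in blue_light. TEAD1 stood at 222 ± 32.4 CPM in blue_light and 27.9 ± 11.6 in RL (n = 3 each, log2 2.99 ± 0.26, adjusted p = 0.000937), and LOC100344965 at 26.6 ± 4.03 and 5.06 ± 0.541 (2.39 ± 0.23, 0.00158), each without overlap of the groups. TEAD1 lost its call in 1 of 23 alternatives, a fit of only these groups (0.0510), and LOC100344965 in 1 (0.0768). The count was 4 without blue_light 2 or without RL 1, 5 without RL 2, 27 by limma with array weights and 81 with DESeq2 (53 up, 28 down). By edgeR 934 genes had an unadjusted p below 0.05. Values without a claim of change were TTC9 (69.3 ± 9.36 in blue_light, 9.13 ± 4.47 in RL), PNPLA6 (34.9 ± 1.02 and 65.1 ± 2.93), PADI4 (5.23 ± 0.983 and 25.4 ± 14.1), the purine enzyme PNP (55.9 ± 6.79 and 87.8 ± 6.66). DIP2C had log2 1.31 ± 0.19 (edgeR adjusted p = 0.0597).

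Cholesterol synthesis genes stood lower in blue_light than in RL in 19 of 19 (camera adjusted p = 9.26e-15; 0.000424 with the set covariate), 9 of them when adjusted over the list alone, but adjusted p = 0.431 with an estimated correlation. HMGCS1 stood at 105 ± 29.6 against 252 ± 51.9 CPM. The same adjusted p = 0.431 with an estimated correlation held for 11 more lists lower in blue_light: immediate early genes (19 of 21, 1.16e-05), epithelium (15 of 21, 0.000822), glycolysis (20 of 27, 0.00408), keratocytes (16 of 21, 0.00462), unfolded protein response (19 of 22, 0.00462), angiogenesis (14 of 20, 0.00473), oxidative stress (21 of 28, 0.00630). They also included collagen processing (15 of 18, 0.0140), heat shock (12 of 18, 0.0171), barrier (15 of 26, 0.0250) and interferon response (16 of 23, 0.0367). Adjusted over the list alone, MMP11 was lower in blue_light (log2 −1.52; edgeR adjusted p = 0.0367) and ASPN higher (8.91 ± 4.29 against 2.23 ± 0.354 CPM; 0.00431). Lens genes (14 of 16, 0.000192) and retinal genes (17 of 19, 0.000993) stood higher, both with adjusted p = 0.460 with an estimated correlation. Omission of blue_light 1 ended the calls of lens (0.751), keratocytes (0.568), angiogenesis (0.161), heat shock (0.0952), collagen processing (0.0880), barrier (0.0871), unfolded protein response (0.0585) and interferon response (0.0585). Omission of blue_light 2 ended interferon response (0.256), and of blue_light 3 heat shock (0.233) and barrier (0.0799). Omission of RL 1 ended lens (0.490), interferon response (0.217) and retina (0.0966), and of RL 2 collagen processing (0.504), keratocytes (0.213), unfolded protein response (0.157) and barrier (0.113). Omission of RL 3 ended oxidative stress (0.211), barrier (0.203), immediate early (0.152), glycolysis (0.151) and heat shock (0.101). Without the 3 retinal libraries retina had 0.00153, and the calls ended were lens 0.803, keratocytes 0.557, angiogenesis 0.272, heat shock 0.126, collagen processing 0.0939, unfolded protein response and barrier both 0.0730, and interferon response 0.0614. Library size as a covariate ended collagen processing (0.612), unfolded protein response (0.387), keratocytes (0.377), glycolysis (0.295), oxidative stress (0.254), barrier (0.117) and angiogenesis (0.0678). The set covariate ended 10 calls: epithelium 0.155, keratocytes 0.346, oxidative stress 0.877, immediate early 0.138, heat shock 0.212, unfolded protein response 0.883, collagen processing 0.934, angiogenesis 0.104, and barrier and glycolysis both 0.976. Among genes of mean FPKM 5 or more the calls ended were interferon response (0.793), heat shock (0.118), retina and collagen processing (both 0.109), barrier (0.103), keratocytes (0.0514), and oxidative stress and unfolded protein response (both 0.0505). Limma after quantile scaling ended glycolysis (0.221), keratocytes and collagen processing (both 0.187), epithelium (0.130) and unfolded protein response (0.0852). Of 6 limma settings, 5 ended retina (0.0638 to 0.220) and barrier (0.0617 to 0.375), and 4 ended oxidative stress (0.0507 to 0.321) and heat shock (0.0557 to 0.395).

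GL against RL gave 13 changed genes of 18171 by edgeR, 4 up and 9 down. TEAD1 stood at 225 ± 23.8 CPM in GL and 27.9 ± 11.6 in RL (n = 3 each, log2 3.01 ± 0.26, adjusted p = 0.000436). SDK1 stood at 22.4 ± 4.86 and 5.14 ± 0.799 (2.13 ± 0.29, 0.0117), HPN at 46.3 ± 11.4 and 16.99 ± 3.71 (1.45 ± 0.23, 0.0409) and DIP2C, named after its values were seen, at 42.3 ± 6.60 and 18.7 ± 2.91 (1.17 ± 0.18, 0.0409). HSPA13 stood lower in GL (14.1 ± 4.09 and 56.0 ± 11.4; −1.99 ± 0.24, 0.00651). The RPL17 copies were lower in GL: LOC100339314 (log2 −4.17, 0.00448), LOC100355297 (−4.37, 0.000436), LOC100350920 (−4.08, 0.00673), LOC100354651 (0.00673; fitted log2 −9.21 to −2.98 over the alternatives). Lower too were LOC100339582 (−3.02, 0.00361), LOC100355319 (0.0277; fitted log2 −6.07 to −2.14), LOC100352781 (4.16 ± 1.54 against 96.4 ± 55.4 CPM; −4.53 ± 0.65, 0.0218) and LOC108178018 (8.86 ± 0.456 against 61.1 ± 35.0; −2.79 ± 0.37, 0.0117). In all 13 the groups did not overlap. DIP2C lost its call in 16 of 23 alternatives (0.0518 to 0.342), HPN in 10 of 24 (0.0518 to 0.520) and SDK1 in 7 of 23 (0.0652 to 0.272). In turn these 3 genes had 0.226, 0.226 and 0.0909 without GL 1, 0.0534, 0.142 and 0.0657 without GL 3, 0.117, 0.122 and 0.0652 without RL 1, 0.177, 0.206 and 0.0889 without RL 3, and 0.0961 for DIP2C without GL 2. Of the copies, LOC100352781 lost its call in 10 of 24 (0.0559 to 0.312), among them GL 1 (0.160), 2 (0.0579) or 3 (0.108) or RL 1 (0.0559) or 3 (0.0636). LOC100355319 lost it in 9 of 23 (0.0515 to 0.379), among them GL 1 (0.214) or 2 (0.0515) or RL 1 (0.0746) or 3 (0.0889). LOC100350920 had 0.0568 without GL 1 and 0.0534 without GL 3, LOC108178018 0.112 and 0.0775, and LOC100354651 0.0901 without GL 1. The count was 5 without GL 1, 24 without GL 2, 8 without GL 3 or without RL 3, 25 without RL 2, 154 by limma with array weights (98 up, 56 down, the opposite majority) and 201 with DESeq2 (92 up, 109 down), and 1562 genes had an unadjusted p below 0.05.

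Immediate early genes stood lower in GL than in RL in 19 of 21 (camera adjusted p = 2.29e-07), but adjusted p = 0.977 with an estimated correlation. FOS (93.8 ± 23.7 and 521 ± 216 CPM; log2 −2.47 ± 0.55), DUSP1 (70.1 ± 26.5 and 314 ± 132) and EGR1 (195 ± 51.0 and 460 ± 123) were lower when adjusted over the list alone. Without RL 3 the list had 0.111. Cholesterol genes stood lower in 15 of 19 (0.0129; adjusted p = 0.977 with an estimated correlation), HMGCS1 (101 ± 39.3 and 252 ± 51.9) and SQLE (71.8 ± 6.45 and 112 ± 17.8) when adjusted over the list alone, though not without GL 2 (0.364), RL 2 (0.655) or RL 3 (0.143) or by limma with a block for replicate number (0.0959). Retinal genes stood higher in 17 of 19 (0.0129; adjusted p = 0.977 with an estimated correlation), though not without RL 1 (0.0652) or RL 3 (0.143), and with the sign turned without GL 3 (0.797) and without the 3 retinal libraries (0.692). They also lost the call with library size (0.0870) or set (0.109) as a covariate and within the 7 libraries (0.0794), among genes of mean FPKM 5 or more (0.400) and in 5 limma settings (0.105 to 0.374). SERPINB10 (19.3 ± 2.48 and 46.9 ± 5.54) and HS6ST2 (0 and 3.23 ± 0.944) are values without a claim of change.

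The mean of the 3 light groups differed from control in 2 genes of 18171 by edgeR. LOC100339782 was higher (adjusted p = 0.000143), seen in all 9 light libraries and in 0 of 3 controls. LOC100344261 was lower (log2 −2.30 ± 0.23, adjusted p = 0.00227; 31.3 ± 10.5 CPM in control against 5.53 ± 0.764, 6.21 ± 1.41 and 7.44 ± 2.48 in blue_light, GL and RL), and lost its call in 1 of 28 alternatives (0.216). AHCY itself stood at 505 ± 28.2, 502 ± 62.9, 765 ± 23.9 and 679 ± 167 CPM. These were also the 2 genes called in at least 2 of the 3 light groups, LOC100339782 in all 3. Over all 4 groups, 11 genes differed by edgeR, 262 by DESeq2, and 1416 had an unadjusted p below 0.05. The mean gave 9 genes without control 1, 7 without GL 2, and 4 without blue_light 2 or without RL 2, 23 by limma with array weights and 55 with DESeq2, with 763 at an unadjusted p below 0.05. Values without a claim of change were the lens genes LENEP (10.5 ± 3.50 CPM in control; 3.59 ± 1.27, 2.84 ± 1.07 and 3.74 ± 1.45) and LGSN (78.9 ± 45.2; 12.1 ± 2.003, 12.1 ± 5.80 and 25.3 ± 20.6).

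For the mean of the light groups, cell cycle genes stood higher in 25 of 31 (camera adjusted p = 3.19e-08), epithelial genes in 20 of 21 (0.00559; 0.0736 without control 1, 0.207 with library size as a covariate, 0.0679 by limma after quantile scaling), and lens genes lower in 16 of 16 (3.35e-13), all with adjusted p = 0.731 with an estimated correlation. For the cell cycle list control 1 (3.78) lay inside the range of the light libraries, 3.32 to 4.04. Cholesterol genes stood higher in 18 of 19 (0.00128; 0.344 without control 1, 0.333 with library size), barrier genes in 20 of 26 (0.0240; 0.158 without blue_light 2, 0.481 without control 1, 0.0568 without RL 3, 0.207 with library size, 0.0679 by limma after quantile scaling) and interferon response genes in 18 of 23 (0.0295), with adjusted p = 0.909 with an estimated correlation. The interferon call ended in 13 of 27 settings, among them omission of blue_light 3 (0.0917), control 2 (0.480), GL 1 (0.0590) or RL 1 (0.0722) or of the 3 retinal libraries (0.316) and the set covariate (0.0546). The rest were genes of mean FPKM 5 or more (0.483) and all 6 limma settings (0.0697 to 0.146). Adipocyte genes stood lower in 4 of 6 (0.00559; 0.122 without control 2, 0.0534 without RL 1, 0.259 without the retinal libraries; adjusted p = 0.568 with an estimated correlation). Adjusted over the list alone, LPL (0.000151) and LENEP (0.00438) were lower, and CCNB1 (0.0261), ARNTL (0.0419) and RARRES1 (0.0188) higher. Clock and opsin genes passed over all genes in no comparison. PER1 stood at 155 ± 49.8 CPM in control, 121 ± 11.4 in blue_light, 79.98 ± 32.4 in GL and 121 ± 31.8 in RL, PER2 at 33.1 ± 11.2, 29.4 ± 5.79, 25.3 ± 14.6 and 19.4 ± 4.71. The lowest edgeR adjusted p was 0.231 for NR1D1, 0.241 for OPN3 and 0.259 for CRY1.

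Of 45 lists tested, 17 were called in at least 1 comparison by camera and 28 in none. With an estimated correlation or by fry no list was called, the lowest adjusted p being 0.377 and 0.342. Lowest camera adjusted p over the comparisons among cell type lists was 0.139 for limbus, 0.0521 for conjunctiva, 0.524 for endothelium, 0.591 for macrophages and 0.605 for neutrophils. It was 0.0510 for T, B and NK cells, 0.0695 for vessels, 0.815 for red blood cells, 0.194 for nerve, 0.0528 for melanocytes, 0.503 for skeletal muscle and 0.211 for myofibroblasts. For light and stress lists it was 0.651 for opsins and cryptochromes, 0.164 for the clock, 0.166 for aldehyde dehydrogenases, 0.524 for DNA damage, 0.546 for apoptosis, 0.142 for inflammatory cytokines and 0.0550 for autophagy. For matrix and signalling it was 0.116 for fibrillar collagens, 0.692 for proteoglycans, 0.0627 for proteases, 0.424 for TGF-beta and 0.605 for mucins. For transport and metabolism it was 0.0695 for ion transport, 0.0989 for retinoids, 0.0695 for oxidative phosphorylation and 0.0510 for ribosomal proteins. Testing for change in either direction, fry gave 0.00478 for retinoids in RL, 0.0297 for retinoids and for nerve and Schwann cells in GL, and 0.0402 for retinoids in the mean.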

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

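All tests of explanations in this part were chosen after the results they measure were seen; the comparisons between light groups and the exchange of labels among libraries were planned.

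The differences below came up because 2 light groups moved apart from the shared control by different amounts, by the edgeR test of the difference itself. TEAD1 was higher in blue_light than in RL (log2 2.99, adjusted p = 0.000937) and higher in GL than in RL (3.01, 0.000436). LOC100344965 was higher in blue_light than in RL (2.39, 0.00158) and than in GL (2.48, 0.00107). HSPA13 was higher in blue_light than in GL (1.96, 0.0124) and lower in GL than in RL (−1.99, 0.00651). Between blue_light and GL, TMEM30B (−1.43, 0.0278) and SPOCK2 (−1.29, 0.0205) were lower in blue_light. Between GL and RL, SDK1 (2.13, 0.0117), HPN (1.45, 0.0409) and DIP2C (1.17, 0.0409) were higher in GL. In each of these the 3 libraries of one group lay apart from the 3 of the other. All 9 edgeR calls of blue_light against GL ended with a covariate for library set (125 by DESeq2 and 1264 genes at an unadjusted p below 0.05), with folds of the same sign. Log2 values ± SE went from 1.96 ± 0.24 to 1.83 ± 0.34 for HSPA13, −1.43 ± 0.21 to −1.37 ± 0.29 for TMEM30B, −1.29 ± 0.18 to −1.03 ± 0.22 for SPOCK2 and 2.48 ± 0.23 to 2.51 ± 0.34 for LOC100344965. Among copies they went from 3.77 ± 0.35 to 3.53 ± 0.50 for LOC100355297, 2.29 ± 0.32 to 2.57 ± 0.46 for LOC100339582, 3.66 ± 0.46 to 2.74 ± 0.53 for LOC100339314, 3.54 ± 0.50 to 2.62 ± 0.59 for LOC100350920 and 7.20 ± 0.94 to 5.96 ± 1.05 for LOC100354651. The calls ended because every SE grew, as the covariate is estimated from control and RL alone, and because some folds shrank. Unadjusted edgeR p with the covariate lay between 9.05e-06 and 0.000864. The set difference was taken from control and RL, which had no part in choosing the 9 genes. It left most of each fold in place, beyond its SE. If the set acts alike in all groups, this argues against the set as the whole cause of these differences. LOC100354651 is left aside here, as its fold depends on the prior count. The folds themselves come from the libraries by which the genes were chosen, and the set difference is imprecise. How much of these 9 differences comes from the set stays open.

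RPL17 copies made up the remaining differences. In blue_light minus GL the log2 values were 3.66 for LOC100339314, 3.77 for LOC100355297, 3.54 for LOC100350920, 7.20 for LOC100354651 and 2.29 for LOC100339582, with edgeR adjusted p from 0.00107 to 0.0205. In GL minus RL they were −4.17 for LOC100339314, −4.37 for LOC100355297, −4.08 for LOC100350920, −7.72 for LOC100354651, −4.53 for LOC100352781, −2.79 for LOC108178018, −3.02 for LOC100339582 and −5.30 for LOC100355319, with adjusted p from 0.000436 to 0.0277. The copies with near-zero counts in GL have folds that depend on the prior count.

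In GL, 6 RPL17 copies fell while LOC108175352 held 92.3% to 93.2% of the family's reads. Lower expression of RPL17 is argued against, since the loss of those copies would need a family sum at log2 −0.86, and the sum differed by −0.17 (SE 0.14). Reads that move between near-identical copies would leave the sum in place, as seen. Shares of the main copy lay at 3 levels, the highest being that of GL. They were 8.34% to 9.54% in control 1, RL 1 and RL 3, and 51.5% to 55.8% in 6 libraries. The low and high levels were taken as means of these same shares, so only their midpoint was put to a test. The 6 libraries lay at most 5.07 points from it, as a sequence variant that the animals carry in 0, 1 or 2 copies would give. That variant stays open without the reads, and with it whether these copies reflect illumination or the animals used. The share by group had an exact permutation p of 0.0181 over 15400 partitions. That p is no support for a link to GL, as the share was examined because copies had been called lower in GL.

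Lens and retina transcripts were uneven over libraries, and the lens list was called lower in GL, in RL and in the mean. Genes of each list moved together within groups (mean correlation 0.865 for lens, 0.686 for retina), as RNA of neighbouring eye tissue in single libraries would bring. The mean log2 CPM of the retina list was 3.79 in GL 3, 1.35 in blue_light 1 and 1.28 in control 2. It was 0.19 in RL 2, −0.142 in blue_light 2 and −0.258 in blue_light 3, and −2.71 to −1.77 in the rest, control 1 and 3 among them. An effect of illumination on the list means cannot be told apart from uneven tissue with 3 libraries a group (exact permutation p = 0.262 for lens and 0.659 for retina). A former bound, replaced because a wide range within groups does not exclude a group effect, had been met: the second-widest range within a group was 2.99 log2 for lens and 3.83 for retina, against ranges of group means of 2.02 and 1.9998. Without the 3 libraries with retinal transcripts the retinal calls ended in GL minus control (0.343) and GL minus RL (0.692, sign turned), but not in blue_light minus control (2.29e-11) or blue_light minus RL (0.00153), so tissue in those 3 libraries does not account for the blue_light calls. Tissue carried over at dissection may underlie part of the lens and retina calls, and an illumination effect on them stays open.

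The 5 libraries with more genes at low counts (blue_light 1 to 3, control 1, RL 1) form the third pattern. Library size is argued against, as after thinning to one total the lowest of the 5 still had 663 more such genes than the highest of the 7. Illumination group as the whole cause is argued against, since 2 of the 4 groups had libraries in both sets. A batch of library preparation or sequencing, which the labels do not give, would bring a shared deviation of control 1 and RL 1 from their groups. Their deviations correlated at 0.538 over abundant genes, with 0.367 the highest of the 8 other pairs of a control and an RL library. Both were also the smallest libraries of their groups (44.4 and 45.9 M counts). Over the same genes the first principal component followed library size within groups (r = 0.895), so this deviation cannot tell a batch from library size. All blue_light libraries lie in one set and all GL libraries in the other, so only control and RL separate set from light. For LOC100344965, control 1 and RL 1 of the set of 5 stood at 4.55 and 5.48 CPM, against 23.6 to 31.2 in blue_light. In the set of 7, control 2 and 3 and RL 2 and 3 stood at 43.0 to 61.2 CPM for HSPA13, against 9.54 to 17.4 in GL, and at 13.7 to 16.9 for TMEM30B, against 24.4 to 32.6. What made the 5 libraries differ stays open.

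Exchanging labels in a 3-against-3 comparison gives 10 splits, too few for a share below 0.05. For blue_light against control the real count was 3 and the highest other 2 (1 split as large), for GL against control 10 and 2 (1), for RL against control 2 and 11 (3), for blue_light against GL 9 and 1 (1), for blue_light against RL 2 and 2 (2), and for GL against RL 13 and 2 (1). The split with 11 genes set control 1, RL 1 and RL 3 against the rest, which points to a structure of the samples. The same 3 libraries had the low RPL17 share. The genes of that split are not listed here and may include RPL17 copies, so the share is no separate support for a wider structure. With the library set as a covariate RL against control gave 3 genes and within the 7 libraries 9. For the mean of the light groups chance was not excluded, with 11 of 100 splits giving at least 2 genes and up to 23. That split took blue_light 2, control 1 and RL 1 as controls, all of the set of 5, which points to a structure of the samples along that set, a grouping other than that of the 3 libraries above, and the count with the covariate was 2. For any difference among the 4 groups the real labels gave 11 genes, above the 8 of the highest other split (1 of 100 splits as large). This does not exclude chance, as the exchange takes the libraries as independent, which the labels do not say. The count was also 5 without GL 1 or without GL 3, and 0 by edgeR without the 3 retinal libraries.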

How the results depend on the processing

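The covariates for library size and library set, the fit of 7 libraries, the omission of 3 libraries with retinal transcripts and the step-divided counts were chosen after the data were seen; the other alternatives were planned. Folds of called genes kept direction and call in 770 comparisons with an alternative and direction alone in 200, and turned in none of the settings run. Genes named without a call stayed so in 1295 and were called in 108. Of called lists 814 kept the call, 356 lost it and 8 turned sign. The median-of-ratios scaling and a minimum of 2-fold left the counts as they were where they apply. Where no reason is given, the cause was not tested.

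Counts are given for blue_light (B), GL (G) and RL (R) minus control (C), the pairs, the mean, any difference, and the genes shared by at least 2 light groups. DESeq2 gave BC 29, GC 147, RC 87, BG 372, BR 81, GR 201, mean 55, any 262, shared 33. Limma with array weights, 2 choices changed at once, gave BC 8, GC 131, RC 39, BG 224, BR 27, GR 154, mean 23, any 188, shared 14, against BC 4, GC 12, RC 3, BG 20, BR 6, GR 17, any 22 for limma on log2(FPKM + 1) without weights. Limma with 0.1 added gave RC 4, BG 19, BR 6, any 18. Limma on TPM gave RC 4, BG 16, BR 5. Limma after quantile scaling, 2 choices changed at once, gave BC 5, BG 15, BR 7, any 18 and 23 lists against 49, where limma on log2(FPKM + 1) without it gave BC 4, BG 20, BR 6, any 22 and 33 lists. Genes of mean FPKM 5 or more (9388 tested) gave RC 1, BG 15, mean 1, shared 1 and 26 lists. No filter (21448 tested) gave BR 5, any 22, and step-divided counts BR 4. Fits of only the groups compared, with fewer libraries for the spread, gave BC 7, GC 28, RC 5, GR 3. Lists fell to 0 with an estimated correlation and with fry.

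Library size as a covariate gave GC 5, BG 2, any 6, and turned keratocytes (0.832) and cholesterol (0.822) in GL minus control. Library set as a covariate gave BG 0 by edgeR (1264 at an unadjusted p below 0.05, 125 by DESeq2), as all blue_light libraries lie in one set and all GL libraries in the other, and turned glycolysis (0.599) and cholesterol (0.520) in blue_light minus GL. The 7 libraries alone gave GC 5 (3 up, 2 down), RC 9 (6 up, 3 down) and GR 8 (2 up, 6 down), which turns the majority in GC. Without the 3 retinal libraries, which leaves 2 in blue_light, control and GL, counts were BC 1, GC 1, BG 0 by edgeR (609 at an unadjusted p below 0.05, 32 by DESeq2), BR 1, GR 2, mean 1, any 0 by edgeR (426 and 64), shared 1, and retina turned in GL minus RL (0.692).

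A block for replicate number gave, with limma, BC 1, GC 17, BG 19, BR 8, any 21, shared 1. Limma with the block lacked 4 of 41 gene calls, LOC100339782 (0.0541) and LOC100344261 (0.0541) in BC, LOC100339782 in RC (0.137) and DIP2C in GR (0.133), of which limma without a block already lacked those in RC (0.130) and GR (0.0984). With edgeR the block ended 8, LOC100344261 in BC (0.115) and GC (0.0543), LOC100355319 in GC (0.0883) and GR (0.0873), TMEM30B in BG (0.0538), and HPN (0.127), LOC100352781 (0.0873) and DIP2C (0.0664) in GR, and the list call of retina in GC (0.0965). Taken over all 4 groups, the numbers did not pair the samples: 8 of 18 pairs across groups correlated above 0.1 (−0.133 to 0.461), and 6 of 12 libraries were closest to their own number. For control and RL alone all 3 pairs were above 0.1 (0.461, 0.267 and 0.1003), pair 1 lying in the set of 5, so a shared number there stays open. The edgeR block gave RC 3 (1 up, 2 down) against 2 and ended no gene or list call in RL minus control.

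Omitting 1 library at a time gave BC 2 to 10, GC 3 to 21, RC 2 to 9, BG 3 to 22, BR 2 to 5, GR 5 to 25, mean 2 to 9, any 5 to 25, shared 1 to 10 and 44 to 65 lists. Any difference gave 25 without control 1, 22 without RL 2, 20 without GL 2, 7 without control 3, 6 without control 2, and 5 without GL 1 or without GL 3; shared gave 10 without control 1, 4 without GL 2, 3 without RL 2, and 1 without blue_light 1, 2 or 3, control 2, control 3, GL 1 or GL 3. The result of list retina, GL minus control, turned without GL 3 (0.356) with a range of 0.000149 to 0.419 over omissions, list retina, GL minus RL, also without GL 3 (0.797, range 1.01e-05 to 0.797), and list immediate early genes, RL minus control, without RL 3 (0.582, range 0.000635 to 0.582).

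Median-of-ratios scaling within edgeR, the scale that DESeq2 uses, left the share of higher genes as it was in every comparison. Quantile scaling within limma moved it from 75% to 80% in BC, 80% to 73.3% in BG, 100% to 85.7% in BR and 41.2% to 38.9% in GR, and not in GC or RC. Other shares moved with the test: in BC from 66.7% to 80% by limma with quantile scaling; in GC from 10% to 37.4% by DESeq2; in RC from 50% to 25% by limma on TPM, 0% by limma on log2(FPKM + 1) with or without quantile scaling and 35.6% by DESeq2; in BG from 77.8% to 61.0% by DESeq2; in BR from 100% to 85.7% by limma with quantile scaling and 65.4% by DESeq2; in GR from 30.8% to 47.1% by limma on TPM (41.2% on log2(FPKM + 1)) and 45.8% by DESeq2, and to 63.6% by limma with array weights (98 up, 56 down), which turns the majority. It also turned in BR in a fit of only these groups (1 up, 2 down, 33.3%) and in GC within the 7 libraries (60%) and without the 3 retinal libraries (1 up).

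Shared controls alone gave correlations of 0.507 (B with G), 0.499 (B with R) and 0.506 (G with R) in 20 simulations, against 0.442, 0.495 and 0.398 observed, and covariances of 0.787, 0.775 and 0.779 against 0.774, 0.775 and 0.818. Genes called in both the same way numbered 2, 1 and 1 (10 in at least 2 comparisons without control 1), against 0.05, 0 and 0 simulated without effects. Independent lists would share 0.000110 higher and 0.000495 lower genes for B with G, 0.000110 and 5.5e-05 for B with R, and 5.5e-05 and 0.000495 for G with R. The 3 controls cannot be split with 2 on each side, so part of the excess over independent lists may come from the shared controls. At this depth a gene below 0.173 to 0.273 CPM could not be told from 0.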

Other observations

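The tests in this part were chosen after the data were seen.

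Library size followed the first principal component of 7835 abundant genes (35.1% of variance), and 4 relations with log2 library size were examined over 12 libraries. The same component also separated the library sets. Libraries with more low counts lay at −33.5 to −0.104 on it and the others at 1.65 to 27.1. Over all libraries it therefore cannot tell library size from library set. For that component r was 0.900 (permutation p = 0.000160, BH 0.000320) and rho 0.853 (p = 0.000880, BH 0.00222), with r = 0.850 without blue_light 1 and control 1. For COL1A1, the main fibrillar collagen of the stroma, r was 0.877 (p = 5.0e-05, BH 0.000200) and rho 0.839 (p = 0.00111, BH 0.00222), with r = 0.818 without them. For the keratocyte list r was 0.803 (p = 0.000250, BH 0.000333) and rho 0.818 (p = 0.00192, BH 0.00256), with 0.707 without them. For the epithelial list r was 0.675 (p = 0.0176, BH 0.0176) and rho 0.713 (p = 0.0115, BH 0.0115), with 0.453 without them. After subtraction of group means r was 0.895, 0.824, 0.695 and 0.496 in the same order, without a test.

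Within the 7 libraries with fewer low counts the first component had r = 0.696 (exact p = 0.0615) and rho = 0.643 (exact p = 0.139), with r = 0.286 without control 2 and control 3. COL1A1 had r = 0.524 (exact p = 0.225) and rho = 0.357 (exact p = 0.444), keratocytes r = 0.503 (exact p = 0.242) and rho = 0.464 (exact p = 0.302), and epithelium r = 0.602 (exact p = 0.131) and rho = 0.429 (exact p = 0.354). Without the same 2 libraries these 3 had r of 0.0923, 0.159 and −0.718. After BH all 4 had 0.242 for r and 0.444 for rho, so none passed within the 7 libraries, and the 5 others alone were not tested.

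18S ribosomal RNA (RN18S) took 0.0790% to 0.5001% of the counts, and the 10 most abundant genes 8.77% to 13.1%. COLEC11 was near the floor in controls (0.366 CPM) and 0.0225, 0 and 0 in blue_light, GL and RL.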
